A study of Mus musculus and Homo sapiens with 27 samples.

How the data were processed

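The series holds 27 sequencing libraries of 3 cell lines in 13 groups. PC9 is a human lung adenocarcinoma line. R1 and ZHBTc4 are mouse embryonic stem cell lines, and ZHBTc4 is built so that doxycycline turns off its expression of Oct4 (Pou5f1). Cells were grown either in standard tissue culture (2D) or as clones enclosed in hydrogel spheres (3D), per the labels. Bulk libraries measured polyadenylated RNA of whole cultures. Droplet libraries were made on the inDrops platform, with single cells in droplets of about 2 nl, or with whole clones in droplets of 4 to 5 nl, a method that the study calls CloneSeq. PC9 cells for the similarity comparison carried a random genomic barcode of 8 bp (UGI), which marks the clone a cell belongs to. Each of those 3 cultures gave an expression library and a second library made with primers near the UGI.

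For the bulk libraries, the authors deposited expected counts and TPM per feature, both estimated by RSEM, per the file headers. The labels name Bowtie2 2.3.4.3, RSEM 1.2.31 and Bowtie without their order. The features are RefSeq transcript accessions on hg38 for PC9, UCSC transcript IDs on mm9 for R1, and Ensembl gene IDs on GRCm38 for ZHBTc4. For the droplet libraries, the authors deposited estimated counts per gene and cell barcode, on hg38 or GRCm38, per the file names and the values. No label says whether these count reads or unique molecules, so intervals from them cover counting error at most. For the UGI libraries, the authors deposited a whole-number count for each pair of cell barcode and UGI, with 2 as the lowest count in each file. No file pairs the PC9 or R1 features with gene names, and no table for them was at hand. Human features are therefore given by ID only and R1 features as counts of features, 22 human gene lists could not be tested, and the genes to be named in every human comparison could not be looked up. For ZHBTc4, 55104 of 55364 IDs matched a symbol in GENCODE M21, which also gave the GRCm38 coordinates.

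Expected counts were rounded to whole numbers. Droplet counts were summed over the barcodes of a library. Barcodes with at least 500 counts were kept, which kept every barcode in every file, since the files hold selected barcodes only. Comparisons used the edgeR 4.0.16 quasi-likelihood test with TMM scaling and filterByExpr, and genes passed at a Benjamini-Hochberg adjusted p under 0.05. Each bulk comparison was fitted alone, since the 3 lines have different annotations. The 6 PC9 droplet libraries were fitted together, as were the 4 ZHBTc4 droplet libraries. A group with 1 library was assumed to vary like the replicated groups in its fit. CloneSeq and single cells of ZHBTc4 at 4 d have 1 library each, so only ratios of CPM with exact Poisson intervals (95%) are given. A count of 0 allows up to 3 counts, and folds against a group with no count are lower bounds over 3 counts of that group's summed total. CPM, counts scaled to library totals, are scaled by TMM as well in the fits. Errors are SD between libraries unless an SE is named, and the depth of each library is given with the results.

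There were 29 mouse gene lists, fixed before the data were examined. They were tested with camera (limma 3.58.1) at an inter-gene correlation of 0.01, where at least 5 members were tested, which left 28 lists in the bulk comparison. The mitochondrially encoded list has no member in the files and gave no result. Genes named in the text follow a rule that was also fixed then, except where said otherwise. It takes the 10 genes each way with the largest change among those that passed, had a mean of at least 10 CPM and no overlap between groups, leaving out predicted, uncharacterised and pseudogene names. It adds up to 4 members with at least 5 CPM from each list that passed, and a fixed set of lineage genes. For the comparison without replicates, it takes the 10 largest ratios each way among genes with at least 100 counts.

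Genes per barcode were compared after rounding the counts to whole numbers, thinning barcodes to 5000 counts and leaving out shallower ones. Medians given without thinning use the counts as deposited, and rounding lowers the median of ZHBTc4 CloneSeq from 3173 to 3114.5 genes. Variability between barcodes was the variance over the mean of the thinned counts, for genes with a mean of at least 0.05, and each list's median was placed among 10000 random lists matched on mean. Similarity of cells was the mean Pearson correlation of 2000 variable genes (log-normalised) over pairs of cells with the same UGI, minus that over pairs with different UGIs. UGI labels were permuted 1000 times within a library as a description. Human cell cycle genes were taken from 1314 Ensembl IDs that come with scran 1.30.0, because the planned lists are by symbol. ZHBTc4 barcodes were clustered with scanpy 1.11.5 (2000 variable genes, 30 principal components, Leiden resolution 0.5). Scrublet marked from 0 to 20 barcodes per library as doublets. None was removed, because a CloneSeq barcode holds several cells by design. Other tools were Python 3.11.15 and R 4.3.3.

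No label says that a replicate number marks a shared culture, so the libraries were treated as unpaired. The alternatives set beforehand were DESeq2 1.42.0, median-ratio and upper-quartile scaling, no filter on low counts, a mean of at least 10 CPM, limma on log2(TPM + 1), the replicate number as a block, other minimum counts per barcode, thinning to 2500 counts for variability, a fit of PC9 CloneSeq and unbarcoded cells without the barcoded libraries, and leaving out each replicate. Alternatives chosen after the data were seen were features with whole counts in every library (within 1e-06), limma voom with sample weights, the replicate block in the PC9 droplet fits, list tests in the ZHBTc4 droplet fit and without each bulk replicate, the ZHBTc4 droplet fit without the CloneSeq library, and leaving out cell barcodes within 1 edit of each other.

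The procedures were tested on simulated counts with 200 changed genes. At the spread estimated for ZHBTc4 bulk, 92% of genes changed 2-fold and 18% of those changed 1.5-fold were recovered among 19082 genes. Each simulated gene and library had the same dispersion. No simulated library stood apart from its group, as 1 real ZHBTc4 bulk library does, so these shares can overstate recovery in the real data. At the spread estimated for PC9 bulk (dispersion 0.524) and R1 bulk (0.510), 0% of genes changed 8-fold were recovered, among 18299 and 12997 features. At a dispersion of 0.02 the same PC9 and R1 designs recovered 98% and 100% of them. For the ZHBTc4 droplet fit (4 d against 24 h), 72% of 2-fold changes were recovered among 17558 genes at the estimated spread. For PC9 CloneSeq against unbarcoded cells, 14% of 4-fold changes were recovered among 21680 genes, and against barcoded cells 46%. Simulated lists of 20 genes changed 1.5-fold were called in 5 of 5 cases among 19094 genes, with 0 false calls. The UGI comparison gave a difference of 0.00126 without a clone effect and 0.484 with one. The latter is far above the mean difference of 0.0668 in the real data, so recovery of an effect of that size was not tested.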

Results

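RNA abundance was measured in bulk and droplet libraries of PC9, R1 and ZHBTc4 cells. The bulk libraries were PC9 in 2D (2) and 3D (2), R1 without the support factors 2i/LIF in 2D (2) and 3D (2), and ZHBTc4 in 3D without (3) and with (3) 2i/LIF. 2i/LIF is the cytokine LIF (1000 U/ml) with the inhibitors PD0325901 (1 µM) and CHIR99021 (3 µM). The droplet libraries were PC9 CloneSeq (2), PC9 single cells in 3D (1), genomically barcoded PC9 single cells (3, each with a UGI library), ZHBTc4 single cells after 24 h of doxycycline in tissue culture (2), and ZHBTc4 CloneSeq (1) and single cells (1) after 4 d of doxycycline in hydrogel.

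Total counts in the PC9 bulk libraries were 21214581 and 15326317 in 2D and 15377157 and 15817335 in 3D. The R1 bulk libraries were shallower, with 1295248 and 3795242 counts in 2D and 3971474 and 2594586 in 3D. The ZHBTc4 bulk libraries held 38335806, 42376744 and 27419541 counts without 2i/LIF and 35440021, 35214752 and 36064207 with it. The PC9 droplet libraries summed to 57747387 and 68921573 counts for CloneSeq, 12583543 for single cells in 3D, and 632009, 4130358 and 5256747 for barcoded cells. The ZHBTc4 droplet libraries summed to 3459380 and 6638449 counts at 24 h, 8510073 for CloneSeq and 10999507 for single cells at 4 d.

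The PC9 bulk comparison asked which genes differ between hydrogel and standard culture. edgeR passed 0 of 17667 features, with 2848 at an unadjusted p under 0.05 and 2 libraries per group. DESeq2 passed 2704 features, 1325 higher and 1379 lower in 3D, while limma on log2(TPM + 1) and limma voom with sample weights passed 0 each. Replicates had a Spearman correlation of 0.840 in 2D and 0.864 in 3D. In the PC9 libraries, 68.2% to 71.9% of the features with a count had a value that was not whole, which RSEM gives where reads are shared between features. Among 3132 tested features with whole counts in every library, a set chosen after the values were seen, edgeR passed 373, of which 226 were higher and 147 lower in 3D. In that set, NM_205545 rose from 2.5 ± 0.0904 to 64.1 ± 5.61 CPM (log2 change 4.66, SE 0.19, edgeR adjusted p = 0.000195), and NM_139211 from 1.28 ± 1.81 to 24.3 ± 1.56 (4.04, SE 0.76, edgeR adjusted p = 0.0244). NM_001964 fell from 136.7 ± 2.53 to 8.15 ± 0.904 (-4.06, SE 0.15) and NM_000584 from 588.0 ± 21.7 to 62.8 ± 1.16 (-3.23, SE 0.12), both with an edgeR adjusted p of 0.000195 (n = 2 per group). The files do not pair these IDs with gene names.

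The R1 comparison asked the same for stem cells kept for 4 d without 2i/LIF. edgeR passed 0 of 12790 features, with 3661 at an unadjusted p under 0.05. DESeq2 passed 3666 (1567 higher and 2099 lower in 3D), limma on log2(TPM + 1) 1189 (614 and 575) and limma voom with sample weights 552 (111 and 441). The median log2 change over all tested features was 0.21 with TMM, and median-ratio scaling shifted it by -0.17. Replicates were less alike than in the other lines, with a Spearman correlation of 0.587 in 2D and 0.795 in 3D. Of 3304 tested features with whole counts, edgeR passed 816, with 372 higher and 444 lower in 3D. The files do not pair the R1 transcript IDs with gene names, and the 2 features each way that the naming rule takes from this set had no count in 1 group, so none is given.

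The ZHBTc4 bulk comparison asked what withdrawing 2i/LIF for 4 d changes in hydrogel, with doxycycline in both groups per the series description, although the sample labels say untreated. Pou5f1 (ENSMUSG00000024406, annotated on GRCm38 chromosome 17, 35506018 to 35510772), which encodes Oct4, lay at 47.4, 49.9 and 48.5 CPM without 2i/LIF and 50.9, 52.6 and 51.6 with it. It did not pass (log2 change -0.09, edgeR adjusted p = 0.597), though each library without 2i/LIF lay below each with it, and the labels leave open whether doxycycline was present. In the droplet libraries, which are made differently, Pou5f1 was at 17.9 and 19.8 CPM after 24 h of doxycycline and at 2.07 after 4 d, so the bulk level does not show that Oct4 was off. Counts per gene ID also do not tell whether they come from the annotated locus or from another copy of the gene. edgeR passed 12 of 19071 genes, 3 higher and 9 lower without 2i/LIF (n = 3 per group). The gene with the largest fall was Cited1 (ENSMUSG00000051159, chromosome X, 102247381 to 102252181), from 440.6 ± 11.3 to 197.5 ± 15.7 CPM (log2 change -1.16, SE 0.09, edgeR adjusted p = 0.0454). Fbp2 (ENSMUSG00000021456, chromosome 13, 62836877 to 62858422), which encodes a fructose-bisphosphatase, rose from 8.80 ± 0.174 to 17.6 ± 1.73 (0.99, SE 0.10, edgeR adjusted p = 0.0457). The hypoxia-responsive peptide gene Adm fell from 19.7 ± 0.725 to 11.6 ± 0.279 (-0.77), and Casq2, Cadps, Olfm2, Ripor2 and Tmtc1 fell with log2 changes from -1.01 to -0.71. The naming rule took only genes that separated the groups without overlap, as 10% of unchanged genes would by chance.

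**Figure D1:**
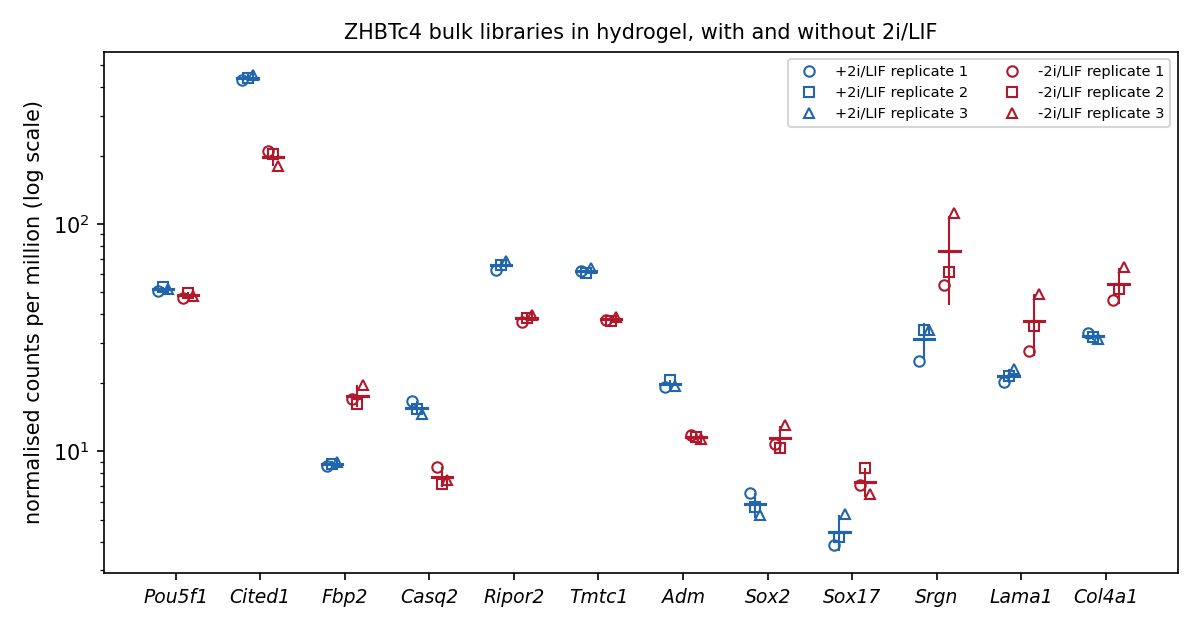
Normalised CPM (log axis) of 12 genes in the 6 ZHBTc4 bulk libraries. Each symbol is a library, horizontal lines are group means and vertical lines SD; Cited1 is at 179.6 to 208.9 without 2i/LIF and 428.9 to 451.4 with it, and Srgn reaches 112.4 in replicate 3 without 2i/LIF.

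The count of 12 changed whichever library was left out, and none of the 12 passed with the replicate number as a block. Without replicate 3 of the group lacking 2i/LIF, edgeR passed 1462 genes, 627 higher and 835 lower, the 12 among them. Leaving out any other single library gave 0 or 1. In all 6 libraries DESeq2 passed 630 genes, 264 higher and 366 lower, and limma on log2(TPM + 1) passed 0. Without that replicate the pluripotency gene Sox2 rose (log2 change 0.85, SE 0.10, edgeR adjusted p = 0.00616), as did the endoderm genes Sox17 (0.81, adjusted p = 0.0196), Col4a1 (0.61) and Lama1 (0.55). The trophoblast gene Ascl2 rose too (0.56, edgeR adjusted p = 0.00462). With all libraries none of these passed, and Sox2 was at 11.4 ± 1.43 without and 5.83 ± 0.677 with 2i/LIF (edgeR adjusted p = 0.0697). The largest changes without that replicate included Phlda2 (1.14) and the glucose transporter gene Slc2a3 (0.71) upward. Downward they included Cldn11 (-1.21) and the chemokine genes Cxcl5 (-1.07) and Ppbp (-1.04). The naming rule was applied to the libraries without that replicate only after the data were seen.

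Of 28 gene lists, camera passed 5 in this comparison, and 0 passed with an estimated correlation (adjusted p from 0.0990 to 0.225). That setting also takes its degrees of freedom from the few libraries, so it has less power whatever the correlation. The estimate was above the preset 0.01 for primitive endoderm (0.0708) and naive pluripotency (0.035). It was below it for ribosomal proteins (0.00886), Wnt targets (-0.0241) and epithelial genes (-0.029). The primitive endoderm list rose, with 23 of 27 members higher and a median log2 change of 0.58 (adjusted p = 1.01e-10, with an estimated correlation 0.137). Cited1 and 3 other members went the other way. The naive pluripotency list also rose, with 20 of 21 members higher and a median of 0.16 (adjusted p = 0.00345, estimated 0.225, without replicate 3 of the group lacking 2i/LIF 0.0462), as did Wnt and beta-catenin targets (10 of 13, median 0.39, adjusted p = 0.00345, estimated 0.188) and cytosolic ribosomal proteins (63 of 73, median 0.23, adjusted p = 2.71e-08, estimated 0.0990). The epithelial list fell (17 of 23 lower, median -0.12, adjusted p = 0.0215, estimated 0.225), but did not pass without replicate 1 (0.075) or 2 (0.0559) of the group lacking 2i/LIF or replicate 1 of the other (0.0545). Its members Dsp and Krt19 had log2 changes of -0.57 and -0.46 and were not called over all genes. Naive pluripotency did not pass with fry (0.0504). Over all genes 0 members of these lists were called higher and 1 lower. Adjusted over the list alone, 17 primitive endoderm genes were called higher and 2 lower, 4 Wnt targets higher, 1 epithelial gene higher and 5 lower, and 0 naive pluripotency and ribosomal genes either way.

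ERK targets (adjusted p = 0.429, median 0.08) and LIF and STAT3 targets (0.752, median 0.10) did not pass by camera. The early trophoblast list had an adjusted p of 0.0655 (median 0.14) and 0.0438 without replicate 2 of the group lacking 2i/LIF. Without replicate 3 of that group, core pluripotency went from 0.137 to 0.0417, trophoblast giant cell and placental from 0.354 to 0.0251, and actin and SRF targets (lower) from 0.164 to 0.00415. With fry, core pluripotency (0.00393), mesendoderm (0.028) and G2 and M phase (0.0167) passed. With all libraries and camera, formative and primed pluripotency had 0.454, mesendoderm 0.164, mesoderm 0.229, neural 0.563 and two-cell-like 0.978. The adjusted p was 0.674 for hypoxia response, 0.164 for glycolysis, 0.409 for cholesterol biosynthesis, 0.164 for S phase and 0.164 for G2 and M phase. It was 0.454 for p53 targets and 0.429 for ATF4 and the unfolded protein response. For YAP/TAZ targets it was 0.645, for extracellular matrix 0.567 and for mesenchymal transition 0.710. Marker lists of other cell types had 0.350 (fibroblast) and 0.354 (blood and immune). Single lineage genes Nanog, Gata6, Cdx2, Gata3, Hand1 and Krt8 had edgeR adjusted p-values from 0.434 to 0.979. Fgf5 and T were under 0.5 CPM in each of the 6 libraries and were not tested.

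CloneSeq barcodes held more counts than single-cell barcodes in the ZHBTc4 line. The ZHBTc4 CloneSeq library had a median of 12419 counts and 3173 genes per barcode (536 barcodes), against 7536 counts and 2762 genes for single cells at 4 d (1189 barcodes), and 5346 and 7307 counts at 24 h (565 and 779 barcodes). The PC9 CloneSeq libraries differed from each other, with medians of 9501 and 61186 counts (669 and 1033 barcodes), and quartiles of 3970 and 153466 counts in the first. PC9 single cells in 3D had a median of 5622 counts (1328 barcodes), and barcoded cells 5049, 23483 and 29418 (113, 154 and 152 barcodes). The first PC9 CloneSeq library therefore lay below 2 of the 3 libraries of barcoded single cells.

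**Figure D2:**
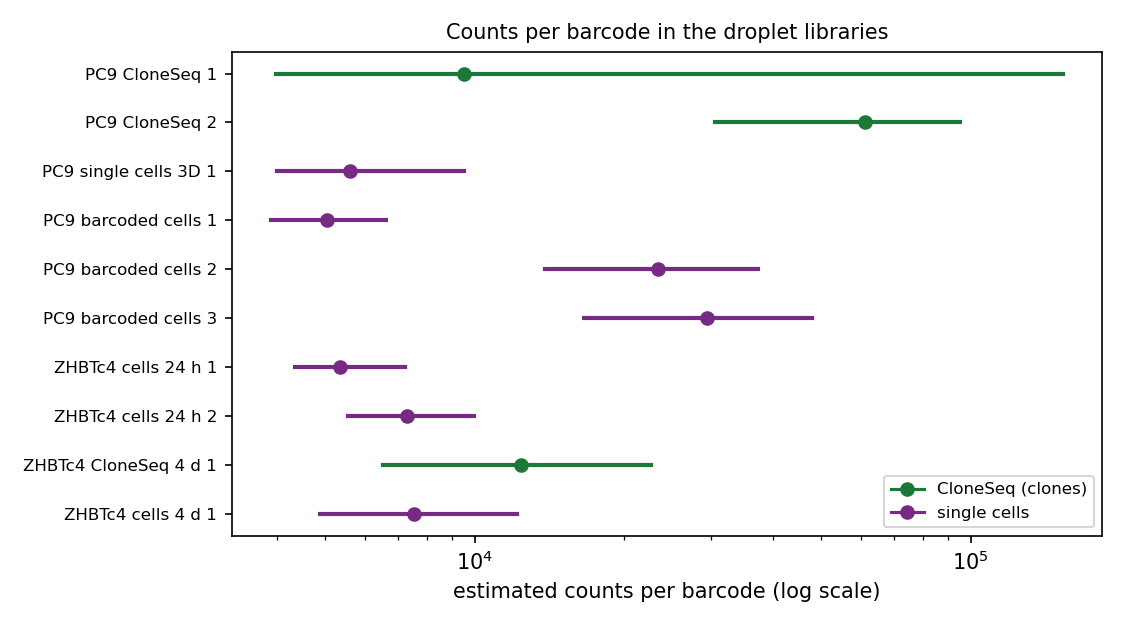
Estimated counts per barcode (log axis) in the 10 droplet expression libraries. Points are medians and lines run from the first to the third quartile; the PC9 CloneSeq medians are 9501 and 61186 and the single-cell medians lie from 5049 to 29418.

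Genes per barcode were also compared at 5000 counts. PC9 CloneSeq barcodes showed medians of 2139 and 2143 genes, single cells in 3D 2152, and barcoded cells fewer, at 2050, 1862 and 1950. ZHBTc4 CloneSeq barcodes showed 1986 genes, no more than single cells, with 2224 for single cells at 4 d and 2037 and 2005 at 24 h. Thinning left out 260 and 107 barcodes of PC9 CloneSeq, 556 of PC9 single cells, 56, 7 and 12 of barcoded cells, 72 of ZHBTc4 CloneSeq, 322 of ZHBTc4 single cells at 4 d, and 232 and 144 at 24 h.

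The PC9 CloneSeq libraries were compared with single cells to ask whether clones and cells grown in hydrogel give the same profile. Against the 1 library of unbarcoded single cells, edgeR passed 8 of 22003 genes, all lower in CloneSeq, and DESeq2 38 (4 higher, 34 lower). The count was 0 without any of CloneSeq replicate 1, CloneSeq replicate 2 or barcoded replicate 1, and 197 and 198 without barcoded replicates 2 and 3. In a fit without the 3 barcoded libraries edgeR passed 1239 genes (530 higher, 709 lower). ENSG00000227836 was at 0.753 ± 0.176 CPM in CloneSeq and 33.1 in single cells (log2 change -5.45, SE 0.59), and ENSG00000281383 at 48.3 ± 2.68 and 1098 (-4.51, SE 0.50), both with an edgeR adjusted p of 0.0249. Barcoded single cells had 0, 0.253 and 0 CPM of the first and 14.2, 12.9 and 7.05 of the second, so both were high in the 1 unbarcoded library only. Against barcoded single cells, edgeR passed 5 genes, all higher in CloneSeq, and DESeq2 942 (441 higher, 501 lower). That count was 0 without barcoded replicate 1, 1 without CloneSeq replicate 1, 951 without barcoded replicate 2 and 2566 without barcoded replicate 3. ENSG00000170385 was at 35.9 ± 1.64 in CloneSeq and 1.2 ± 0.857 in barcoded cells (4.94, SE 0.61, edgeR adjusted p = 0.0399), but at 20.2 in unbarcoded single cells. ENSG00000283907 was at 190.9 and 43.8 in the CloneSeq libraries and 0.926 ± 0.460 in barcoded cells (7.26, edgeR adjusted p = 0.0241), and at 273.0 in unbarcoded single cells. Genomic barcoding and the method go together in this contrast. Correlation between libraries was 0.983 (Spearman, across genes) for the CloneSeq pair, 0.950 and 0.962 between CloneSeq and unbarcoded cells, and 0.823 to 0.851 among the barcoded libraries.

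The ZHBTc4 droplet libraries addressed the loss of Oct4. Pou5f1 fell from 17.9 and 19.8 CPM at 24 h to 2.07 in single cells at 4 d (log2 change -3.19, SE 0.35), and was at 1.65 in CloneSeq at 4 d. edgeR passed 8833 of 18253 genes between 4 d and 24 h, 4824 higher and 4009 lower, and DESeq2 passed 3313, all of them among the 8833. The pluripotency genes Nanog (172.8 ± 11.4 to 12.7 CPM), Esrrb (111.8 ± 2.31 to 11.7), Zfp42 (159.7 ± 17.3 to 23.8) and Fgf4 (140.7 ± 15.2 to 3.11) fell. Dppa5a fell from 8600 ± 105 to 601.1 and Sox2 from 76.3 ± 6.83 to 27.7. Trophoblast genes rose: Hand1 (ENSMUSG00000037335, chromosome 11, 57828705 to 57832818) from 2.37 ± 0.137 to 100.9, Krt8 from 109.5 ± 3.01 to 1600, the imprinted RNA H19 from 1520 ± 7.73 to 38680, Dlx3 from 2.01 ± 1.53 to 93.9 and Cdx2 from 5.30 ± 0.365 to 22.9. Each of these genes passed in edgeR. Gata3 rose less, with a log2 change of 0.66 and passed too, and Gata6 did not pass (0.20, edgeR adjusted p = 0.313). The 24 h values are means of 2 libraries and the 4 d value is 1 library, so its spread is taken from the 24 h pair, with 1 residual degree of freedom and pooling across genes. The p-values and the count of 8833 rest on that assumption. The 24 h cells grew in tissue culture and the 4 d cells in hydrogel, and time and culture cannot be told apart.

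Some genes had no count on 1 side. In single cells at 4 d, Serpinb9e was at least 286-fold, Exoc3l4 at least 98.8-fold and Ccl2 at least 78.3-fold higher than at 24 h, and Fam25c was at least 109.7-fold lower, each over a floor of 3 counts of the group. CloneSeq at 4 d had 8.37 CPM of Serpinb9e, where single cells had 74.3, and 24.1, 13.7 and 0.943 of the other 3. Other large changes were the interferon-induced gene Rsad2 (1.01 ± 0.746 to 191.9 CPM) and Glis1 upward, and Stmn2 (258.7 ± 2.94 to 2.23), Ngfr, Ooep and Ly6i downward.

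**Figure D3:**
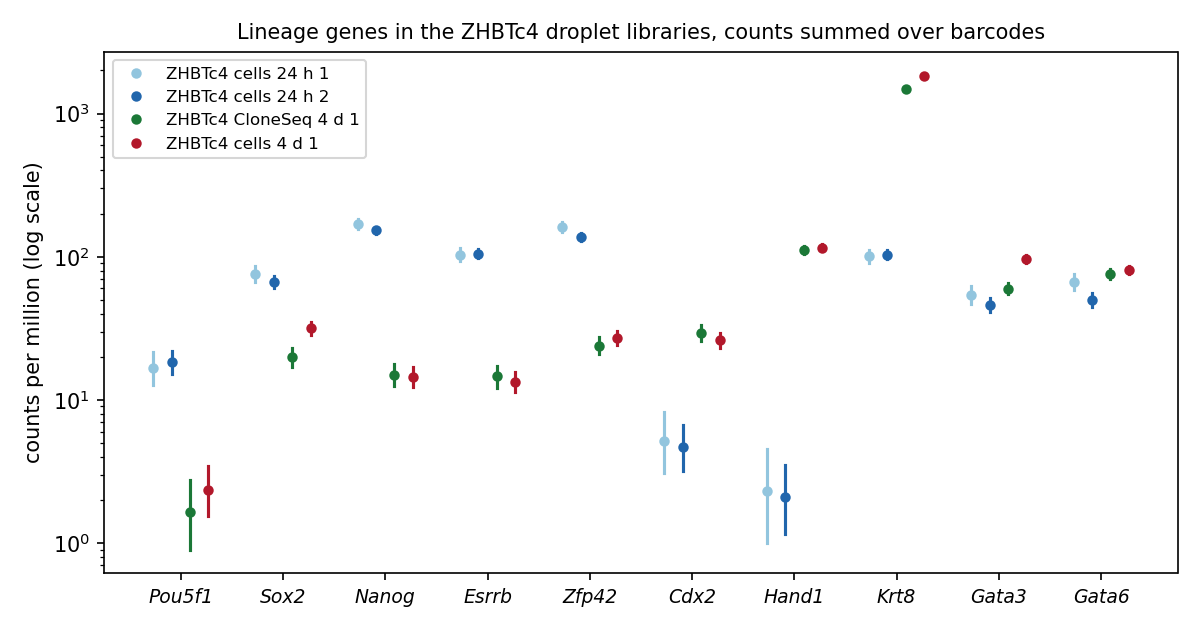
CPM (log axis, not scaled by TMM) of 10 lineage genes in the 4 ZHBTc4 droplet libraries, with counts summed over barcodes and exact Poisson intervals (95%, counting error only). Pou5f1 is at 16.8 and 18.4 at 24 h and at 1.65 and 2.36 in the 4 d libraries, and Krt8 at 100.6 and 103.5 against 1477 and 1826.

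Of 27 gene lists in this comparison, a test added after the data were seen, camera passed 12. With an estimated correlation 0 passed (adjusted p = 0.686 for each of the 12). That setting rests on the 1 residual degree of freedom of the fit and could hardly pass any list, so it cannot decide. Naive pluripotency fell (19 lower, 3 higher of 22 members called, median log2 change -2.12, adjusted p = 1.24e-09), as did core pluripotency (5 lower, 2 higher of 9) and cytosolic ribosomal proteins (72 of 73 lower, median -1.28, adjusted p = 1.52e-28). S phase (19 lower, 7 higher of 43) and G2 and M phase (14 lower, 6 higher of 54) fell by medians of 0.33 and 0.19 on the log2 scale. Early trophoblast genes rose (27 called higher, 4 lower of 32, median 2.16, adjusted p = 6.9e-11), as did epithelial genes (19 higher, 0 lower of 22, median 2.33, adjusted p = 2.58e-11). Actin and SRF targets (15 higher, 1 lower of 20, median 1.38), YAP/TAZ targets (12 higher, 2 lower of 20, median 0.99) and p53 targets (11 higher, 1 lower of 18, median 0.52) rose too. The two-cell-like list rose with 13 of 13 members called higher and a median of 3.66 with genes lacking counts at their bound. It had 5 members with no count in 1 group. The trophoblast giant cell list rose with 8 of 12 called higher, 1 called lower and a median of 2.59 on the same terms. For the lists that passed, the counts adjusted over the list alone differed by at most 2 genes from these.

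CloneSeq and single cells of ZHBTc4 at 4 d had a median absolute log2 ratio of 0.37 over 11602 genes. Their Spearman correlation was 0.950 and their chi-square per degree of freedom 46.0, against 0.977 and 3.71 for the 24 h pair. There is no replicate, so these values compare 2 libraries and not the methods. Fthl17d was 11.2 times (6.68 to 20.2) and Tesc 8.22 times (6.14 to 11.2) as high in CloneSeq, while Serpinb9f was at a ratio of 0.0736 (0.0396 to 0.126), Pgm2l1 at 0.0919 (0.0746 to 0.112) and Serpinb9e at 0.0984 (0.0762 to 0.125). Fthl17 and Serpinb9 are families of related genes, and how reads were divided among them is not known. Pgm2l1 was also high in a cluster of shallow barcodes described below as cluster 3 (341.6 against 48.3 CPM in the other barcodes). That cluster held 268 of 1189 single cells at 4 d and 25 of 536 CloneSeq barcodes. Whether the ratio of Pgm2l1 comes from those barcodes was not tested. Lineage genes, which were not picked by their ratio, had ratios of 0.809 (0.791 to 0.827) for Krt8, 0.965 (0.886 to 1.05) for Hand1, 1.13 (0.947 to 1.34) for Cdx2, 0.618 (0.555 to 0.688) for Gata3 and 0.631 (0.523 to 0.761) for Sox2. Pou5f1 had a ratio of 0.696 (0.336 to 1.38). Of 24 lists, cytosolic ribosomal proteins stood highest (67 of 73 members higher in CloneSeq, median log2 ratio 0.55, percentile 100 of matched random lists). Primitive endoderm (99.9), hypoxia response (99.8), two-cell-like (99.4) and extracellular matrix (99.2) also lay above the random range, and neural (0.880) and early trophoblast genes (1.23) below it.

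Variability between barcodes at 5000 counts was described per library. The median variance over mean was 1.54 in ZHBTc4 CloneSeq, 1.39 in single cells at 4 d and 1.2 and 1.26 at 24 h. The early trophoblast list lay above its random range in each of the 4 libraries. So did naive pluripotency at 5000 counts, but at 2500 counts it lay within the range in the 24 h libraries (percentiles 87.5 and 97.1). At 5000 counts 6 lists did in CloneSeq, the other 4 being two-cell-like, primitive endoderm (within the range at 2500 counts, 91.0), extracellular matrix and epithelial. In single cells at 4 d 12 lists did at 5000 counts and 8 at 2500. Cytosolic ribosomal proteins lay below the range in each library. In PC9 the median was 1.44 and 1.26 in CloneSeq, 1.42 in single cells in 3D and 1.25, 1.48 and 1.36 in barcoded cells. The human cell cycle IDs stood at percentile 99.2 in CloneSeq replicate 1 and within the random range in the other 5 libraries, and replicate 1 fell within it too at 2500 counts (87.5).

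Cells that share a UGI were compared to ask whether cells of a clone are more alike than others. The UGI with the highest count in a cell was assigned, without ties, to 107 of 113, 142 of 154 and 126 of 152 cells. Most cells held several, with medians of 4, 3 and 2 UGIs per cell, and only 12, 41 and 55 cells held 1. The highest UGI took a median of 82.5%, 86.6% and 93.9% of a cell's UGI counts, so clone labels are not free of doubt. There were 14, 20 and 18 clones of at least 2 cells, which gave 28, 35 and 31 pairs. The mean correlation of pairs with the same UGI exceeded that of other pairs by 0.0822 in replicate 1, 0.0158 in replicate 2 and 0.102 in replicate 3 (mean 0.0668 ± 0.0453, SD, n = 3). Of 1000 permutations, 0, 158 and 0 gave as large a difference, so replicate 2 did not stand apart. Without replicate 2 the mean was 0.0922, and without replicate 3 it was 0.0490. The correlations themselves were small, at 0.0724, 0.00892 and 0.0944 for pairs with the same UGI.

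**Figure D4:**
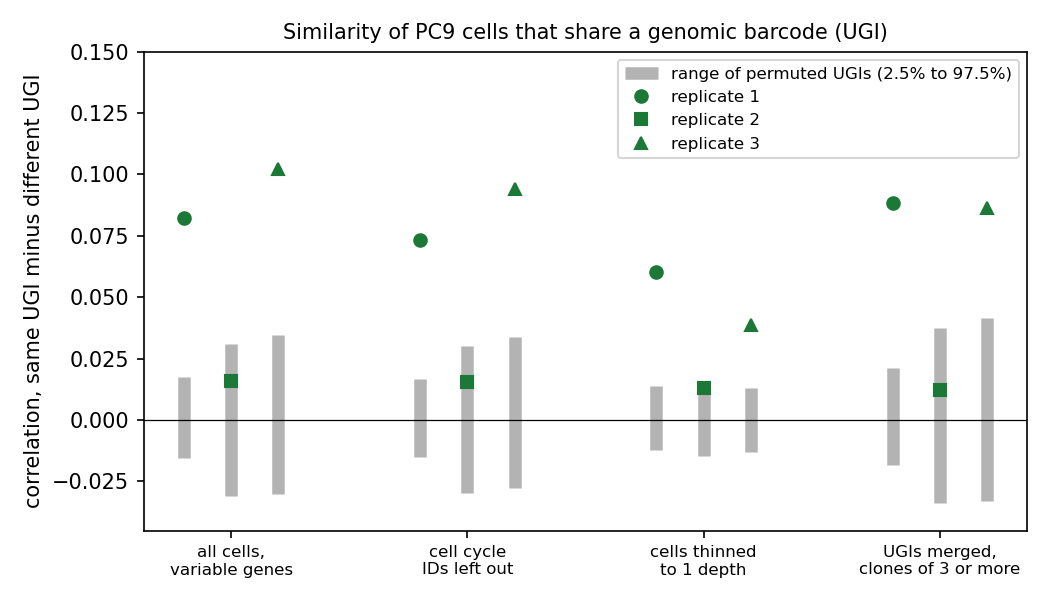
Difference in mean correlation between PC9 cell pairs with the same and with different UGIs, for 3 libraries under 4 settings. Grey bars are the central 95% of 1000 permutations of the UGI labels; replicates 1 and 3 lie above it in each setting shown and replicate 2 within it.

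The 4 ZHBTc4 droplet libraries together gave 7 clusters. By the fixed markers, clusters 0 and 5 were pluripotent-like (9 of 10 markers higher than in the other barcodes) and clusters 2 and 3 trophoblast-like (8 of 10). Cluster 0 held 497 and 715 barcodes of the 24 h libraries, 7 of CloneSeq and 0 of single cells at 4 d. For cluster 5 these were 63, 62, 1 and 2. Clusters 1, 2 and 3 held 0 barcodes of the 24 h libraries. The marker names therefore partly repeat the contrast of 4 d with 24 h, where time and culture cannot be told apart. Cluster 5 was led by Gm3379, Rpl10-ps6 and Rpl10-ps5 and cluster 3 by CT010467.1 and Lars2, none of them a marker. The median log2 fold of the trophoblast markers was 1.71 in cluster 2 and 0.83 in cluster 3. Barcodes of cluster 3 were shallow, with median rounded counts of 4467.5 against 7530 for all single cells at 4 d and 5810 against 12408 for all of CloneSeq. The name of cluster 3 is therefore less certain. Cluster 4 was two-cell-like by 4 markers (Zscan4f, Tcstv1, Tcstv3 and Usp17le), each found in few barcodes. Cluster 1 had only Cdx2 and Hand1 of the trophoblast markers higher and stays unnamed, as does cluster 6 with 14 barcodes. Beyond the numbers given, shares are not compared between libraries, because the genes that define the clusters are those that differ between them.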

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

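No result met the rules set for this part, which need groups of at least 4 libraries, 2 groups under the same contrast, or measurements outside the comparisons. The 3 patterns below were weighed because the report's counts depend on them. The tests of a few abundant genes and of shared reads in PC9 and R1 were chosen only after the result was seen, and thinning and leaving out cell cycle genes, set beforehand as alternatives, were made tests of depth and cell cycle within clones only then.

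Replicate 3 of the ZHBTc4 bulk libraries without 2i/LIF stood apart from the other 2. Replicates 1 and 2 had a chi-square per degree of freedom of 5.61 and pairs with replicate 3 had 91.6 and 100.2, and without it the count of genes rose from 12 to 1462. Lower depth is argued against by a chi-square ratio of 18.55 with all libraries thinned to its total, and shared reads by a ratio of 17.49 among features with whole counts. A library with 2i/LIF under the wrong label would lie near 1 on the genes called without it, but it lay at a median of 0.204 (quartiles -0.395 and 0.921, with 38.0% of genes beyond halfway, against at least 99.2% in each library with 2i/LIF), its top 10 features held 6.69% of its counts, the lowest share of the 6, markers of fibroblasts and blood cells had a median log2 ratio of -0.17 (9 of 17 detected), and gene length and GC content took 0.573% of the variance of its deviation. What sets it apart stays open, no biological explanation was tested because the labels give none, and the p53 list had the largest median deviation in it (0.32, 14 of 18 members higher).

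PC9 cells with the same UGI were more alike in 2 of 3 libraries, with a mean difference in correlation of 0.0668 ± 0.0453. To test for a single cell read under 2 cell barcodes, pairs were set against 2 random parts of the counts of 1 cell. Of 94 pairs, 0% reached the range of correlations found between such parts. If the counts are reads, the 2 parts can hold copies of the same molecules, which 2 barcodes would not. The test therefore cannot decide. Thinning cells to the same number of counts left a mean of 0.0372 and leaving out cell cycle genes left 0.0609, with replicates 1 and 3 above their permuted range in each case. Neither the number of counts per cell nor the cell cycle genes left out account for all of the difference. If the counts are reads, thinning does not even out the molecules per cell, so depth in molecules stays open. Genes that remain can still follow cell cycle phase, so phase itself stays open. Part of the difference may still come from depth, as thinning also adds noise to every correlation. Expression passed on within a clone is a hypothesis that stays open, and replicate 2 (0.0158) did not show it.

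edgeR passed 0 features in the PC9 and R1 bulk comparisons, with 2848 and 3661 at an unadjusted p under 0.05, where DESeq2 passed 2704 and 3666. Reads shared between features may account for the spread behind this. The dispersion of features with whole counts was 0.0361 times that of other features of the same mean in PC9 and 0.252 times in R1, against 0.682 in ZHBTc4. In R1 the features with whole counts kept a dispersion of 0.170, so a second source of spread stays open there, and no biological explanation was tested.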

How the results depend on the processing

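Features with whole counts, voom with sample weights, the replicate block in the PC9 droplet fits, list tests without single replicates and in the droplet fit, the ZHBTc4 fit without CloneSeq, and leaving out cell barcodes within 1 edit were chosen after the data were seen. For single genes and lists, 1122 values kept their side of the threshold or, for ratios, stayed within the main interval. A call was gained by 55 and lost by 73, and 0 reversed among those called in either setting. Direction was not compared where neither setting passed. The p53 list, for example, went from a median log2 change of 0.093 to -0.044 without replicate 3 of the ZHBTc4 bulk group lacking 2i/LIF. For the answers to the comparisons, 100 values stayed within the bounds set and 43 moved. Both tallies include the settings with other minimum counts per barcode. Those settings kept every barcode, except that a minimum of 1000 counts kept 1032 of 1033 in PC9 CloneSeq replicate 2. Their values could therefore hardly move and test nothing. The cause was not tested unless given.

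With DESeq2, the counts were 2704 (PC9 bulk), 3666 (R1 bulk), 630 (ZHBTc4 bulk), 38 (PC9 CloneSeq against unbarcoded cells), 942 (against barcoded cells) and 3313 (ZHBTc4 at 4 d against 24 h). Among features with whole counts they were 373, 816 and 34 in the 3 bulk comparisons, where fewer features were tested and dispersion was lower. Limma on log2(TPM + 1) gave 1189 for R1 and 0 for ZHBTc4 bulk (2761 at an unadjusted p under 0.05), and voom with sample weights 552 and 2951. Without a filter on low counts, the counts were 24 (R1), 40 (ZHBTc4 bulk), 329 and 1497 (PC9 CloneSeq against unbarcoded and barcoded cells). Median-ratio scaling gave 15 for PC9 CloneSeq against unbarcoded cells, and a fit without the barcoded libraries 1239.

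No label says that replicate numbers mark shared cultures. With the replicate number as a block all the same, the counts were 2 for ZHBTc4 bulk, with 0 of the 12 genes among them, and 77 and 1476 for PC9 CloneSeq against unbarcoded and barcoded cells. Deviations from the group means correlated from -0.0553 to 0.0537 for bulk libraries with the same number, and 0 of the 6 ZHBTc4 bulk libraries correlated best with its own number. For PC9 CloneSeq and barcoded cells, in a check added after the data were seen, they correlated by -0.0354 and -0.0974. The lone library of unbarcoded cells could not be checked. No paired analysis was possible for ZHBTc4 at 4 d against 24 h, because 4 d has 1 library.

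Leaving out 1 library gave 0 to 1462 genes for ZHBTc4 bulk, 4 to 8 lists, 0 to 198 and 0 to 2566 genes for PC9 CloneSeq against unbarcoded and barcoded cells, and a mean difference of 0.0490 to 0.0922 for cells with the same UGI. A lone library was assumed to vary like the others. The 24 h replicates were not left out in turn, since no residual degrees of freedom would remain. The highest values came without replicate 3 of the group lacking 2i/LIF, without barcoded replicate 3 (both PC9 contrasts) and without UGI replicate 2.

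With an estimated correlation 0 lists passed in the ZHBTc4 bulk and droplet comparisons, and fry passed 0 in the latter. The droplet fit has 1 residual degree of freedom, which leaves both settings little power there. At 2500 counts, the cell cycle IDs of PC9 CloneSeq replicate 1 stood at percentile 87.5, within the random range. Leiden resolution 1.0 gave 13 clusters, as a higher resolution is built to do. Leaving out cell cycle genes tested nothing for the clusters, since 0 of 97 were among the variable genes.

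Depth limits how many barcodes can be compared. At 5000 counts, 56 of 113 cells of barcoded PC9 replicate 1, 556 of 1328 PC9 single cells and 232 of 565 ZHBTc4 cells of 24 h replicate 1 were too shallow to use.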

Other observations

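The counts of other splits of the libraries were chosen as tests only after the result was seen. Splitting the 6 ZHBTc4 bulk libraries in other ways makes 10 splits, the real one included, which is too few for a share under 0.05. The real split gave 12 genes and the highest other 1, and 5 lists against 2, so in each case 1 split of the 10 gave as many.

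Some features hold the same value to 4 digits. In the 14 barcodes of cluster 6 of the ZHBTc4 droplet data, 9 pseudogene entries from Rps12-ps6 to Rps12-ps18 each stood at 336.9 CPM, against 0.0679 in the other barcodes.

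In cluster 3, CT010467.1 stood at 23770 CPM against 2129 in the other barcodes, and Lars2 at 399.7 against 38.0.

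Placental prolactin genes had few counts. Prl2c2 had 51 counts in CloneSeq, 6 in single cells at 4 d and 0 in the 24 h libraries, Prl3d1 had 23 in CloneSeq and 0 in the other 3, and Prl3b1 had 0 in CloneSeq and 3 in single cells at 4 d. They were chosen after their values were seen, and the CloneSeq library has no replicate.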
